A study of Mus musculus with 8 samples.

How the data were processed

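Two-colour cDNA arrays measured liver RNA of Abcb4-/- mice against a pool of wild-type liver RNA. Per the labels, mutant RNA was in Cy5 on 4 arrays and in Cy3 on 4 arrays, with 1 array of each orientation for each of 4 mice, and cDNA was labelled indirectly. The pool is described as RNA of 4 animals in the sample labels and of 6 in the labelling protocol. The pool was the only control sample, so mean ratios were tested against 0 and p-values leave out the spread among wild-type mice. The mice are separate animals, and the number of arrays limits the precision. Intensities were not used here, so signal over background is unknown for each probe.

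The deposited values are log2 ratios with 1 constant per array. The log2 scale was read from the values, since low-signal probes take the ratios of small whole numbers once the array's constant is removed. Scanner, background correction, normalization and direction are not given in the sources used here, and scale and centring were not stated. Medians of the columns, in the order mouse 1 Cy5, mouse 1 Cy3 and so on to mouse 4 Cy3, were 0.023, -0.023, 0.054, -0.060, 0.069, 0.078, 0.081 and -0.031. Values larger than 15 in size, between 19 and 83 per array, equalled the array's constant plus the log2 of 100000 and were left out as placeholders for a ratio with no signal in 1 channel. They were positive on all arrays with the mutant in Cy5 and negative on all arrays with the mutant in Cy3.

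The 2 columns of mouse 1 summed to 0 within 0.012 on all 20577 probes measured, with a correlation of -1.00 over probes. They were taken as 1 hybridisation entered with both signs. As their mean is 0 by construction, mouse 1 was left out and n is 3 mice.

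The rule for the direction of the columns, written before the data were examined, was to use them as deposited where the 2 arrays of each mouse correlate above 0 and to turn those with the mutant in Cy3 where they correlate below 0. Over all values, placeholders included, the correlations of mice 1 to 4 were -1.00, -0.238, -0.220 and -0.264, which read literally turns the columns. Without placeholders they were 0.100, -0.132 and 0.007 for mice 2, 3 and 4, and the rule gives no answer. The columns were used as deposited, a departure from the literal reading that was chosen after the columns were seen and before any feature was tested. The basis is that the copy of the mouse 1 column under the Cy3 label carries the opposite sign, as do the placeholders on the arrays with the mutant in Cy3, which a sign change made for those arrays would give. The direction remains likely, not stated, and the turned columns were fitted as an alternative.

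Probes were named through the platform annotation, with symbols updated by Entrez identifier against the GRCm38.p6 gene table. Of 20794 probes, 12771 had 1 symbol, 0 had several and 8023 were unnamed here, which gave 9030 genes and 17053 features. All 12771 symbols already equalled those of the table. Of the 1314 list symbols 19 were updated through synonyms. Probes of 1 gene were averaged per array, unnamed probes were kept on their own, and a feature needed both orientations in 3 mice. The names could not be checked against scanner files.

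Means were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg, threshold 0.05). The 30 gene lists were written before the data were examined and tested with camera at a preset correlation of 0.01, where at least 5 members were measured. The named genes were fixed by rule before the data were examined: Abcb4 and its relatives, the 15 named genes with the largest increase and the 15 with the largest decrease past the threshold with 1 sign on all arrays (or all, if fewer), per list the 2 members with the lowest p where none passed, and a set of genes of bile, fibrosis and lipid metabolism, some of which are not reported here. The dye effect was tested on the differences between orientations of the 3 mice, since that of mouse 1 is void.

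The fit was tested on simulated values of 3 mice for 16796 features, 100 of them changed by each size. It recovered 23 of the 100 features changed by 0.5 and 66 of the 100 changed by 1 on the log2 scale, with 0 false calls, and called 0 features where none was changed. A list shifted by 0.15 was called and no other list was. The simulated features were independent of one another, with no dye effect and no shared pool. These counts therefore do not give the rate of false calls, or the sensitivity of the list test, on the real arrays. The alternatives tried were leaving out each mouse, median centring, scaling, all arrays of mice 2 to 4 with mouse as a random block and a dye term, each orientation alone, single probes, other rules for missing values, leaving out features with a dye effect, a variance trend with robust estimation, mouse weights, other thresholds, an unmoderated test, other list tests and the sign of all arrays turned. Those planned for 4 mice or 8 arrays were run on mice 2 to 4. Turned Cy3 columns, mouse 1 from either column, mouse 3 from its Cy5 array and placeholders kept were added after seeing the data.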

Results

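The series profiled liver RNA of male Abcb4-/- mice on the Balb/cByJ background at 17 weeks of age. Abcb4 encodes the canalicular transporter that moves phosphatidylcholine into bile, and the question was how its loss alters gene expression in the liver. Liver RNA of 4 mutant mice was hybridised to 2-colour cDNA arrays against 1 pool of wild-type liver RNA, with 2 arrays of exchanged dyes per mouse, which gave 8 samples. The pool held RNA of 4 animals by the sample labels and of 6 by the labelling protocol. Each array held 20794 probes, of which between 20577 and 20738 had a usable log2 ratio. Values are log2 ratios averaged over both dye orientations of a mouse, and positive ratios are likely mutant over wild type. The overall sign is not stated and rests on the mutant being channel 1 of every sample; that the columns of both orientations run the same way rests on the signs of placeholder values and of the mouse 1 copy. The columns of mouse 1 were sign-turned copies of 1 another, so they counted as 1 hybridisation with no dye swap, and the comparison used mice 2 to 4.

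The targeted gene was read first. The 1 probe named Abcb4 had a log2 ratio of -0.27 ± 0.33 (SD, n = 3) and did not pass the test, with a limma adjusted p of 0.530. Its values on the 6 arrays ran from -1.20 to 0.07, so the spread between arrays was larger than the mean. The lowest came from the array of mouse 3 with the mutant in Cy3, and the mean was -0.08 without mouse 3 and -0.09 with mouse 3 taken from its Cy5 array alone. Which part of the gene was deleted, and whether this probe lies in it, is not given in the sources used here, so the probe checks no label. Abcb11, the bile salt export pump of the hepatocyte, had a ratio of 0.14 ± 0.10 (SD, n = 3), with a limma adjusted p of 0.618. No probe was named Abcb1a or Abcb1b.

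Between mutant livers and the wild-type pool, 56 of 16796 features passed the threshold, 45 with positive and 11 with negative ratios. Positive is likely higher in the mutant. With the sign of all arrays turned, the counts become 11 higher and 45 lower by construction. The split differed between dye orientations. On arrays with the mutant in Cy5 alone 38 features were higher and 1 lower. On those with it in Cy3 alone 5 were higher and 13 lower. Dye, array offsets and the wide spread of the mouse 3 Cy3 array (SD 0.561) were not told apart. Of the 56, 29 were named genes and 27 were probes without a name. Among named genes with 1 sign on all 6 arrays, the highest ratios belonged to Rnh1, the cytosolic ribonuclease inhibitor, at 1.22 ± 0.12 (SD, n = 3), a 2.34-fold difference with a limma adjusted p of 0.0098, and to Ugp2, which makes UDP-glucose for glycogen synthesis, at 1.12 ± 0.33 (SD, n = 3), a 2.18-fold difference. The lowest ratio among these named genes belonged to Kpna4, an importin of the alpha family, at -1.09 ± 0.19 (SD, n = 3), a 2.13-fold difference with a limma adjusted p of 0.0112. The test set mean ratios against 0, so the spread among wild-type animals was not part of it. When the arrays with the mutant in Cy3 were turned and all 4 mice used, 44 features passed, all with positive ratios. Of these, 0 were among the 56. Turning takes the difference between the orientations of mice 2 to 4. Features with like ratios in both then come near 0, so a small overlap follows by construction. Mouse 1 entered that fit with its 1 hybridisation, without a dye swap. After median centring 3 features passed in it.

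Several further genes had higher ratios on all 6 arrays. Ftsj3, which acts in ribosomal RNA processing, reached 0.99 ± 0.04, and Dxo, a decapping exoribonuclease, 0.86 ± 0.15 (SD, n = 3 each). The SDs are of mouse means over both orientations and leave out differences between the arrays of a mouse. Ftsj3, for example, was at 0.70 and 1.19 on the arrays of mouse 3. Trmt2b, a methyltransferase of mitochondrial RNA, was at 0.67 ± 0.18, and Slc25a16, a mitochondrial carrier, at 0.85 ± 0.11. Among genes of immune cells and signalling, Mmd was at 0.95 ± 0.16, Tnfaip8l2, a negative regulator of immune receptor signalling, at 0.93 ± 0.04, and Csf3, which encodes the granulocyte colony-stimulating factor, at 0.86 ± 0.25. Of membrane proteins, Fxyd1, a regulator of the sodium pump, reached 0.92 ± 0.18 and the water channel Aqp4 0.71 ± 0.15. Togaram2 was at 0.83 ± 0.12, Dnmt3l, a cofactor of DNA methylation, at 0.82 ± 0.10, Snf8, a subunit of the ESCRT-II complex, at 0.72 ± 0.21, and Anxa8, an annexin, at 0.69 ± 0.07. Lower ratios on all 6 arrays were found for Wnt2b, a Wnt ligand, at -0.79 ± 0.21, Adipor2, an adiponectin receptor, at -0.74 ± 0.07, and Tmem106c at -0.53 ± 0.02. For Adipor2 the 2 probes differed, with -1.51 ± 0.16 for one and 0.04 ± 0.15 for the other, and for Fxyd1 they stood at 1.35 ± 0.40 and 0.48 ± 0.03. The ratio of Wnt2b rests on unequal sets of probes on the arrays, and its probe that was measured on all of them had -0.67 ± 0.55 with a limma adjusted p of 0.200. Wnt2b, Adipor2 and Snf8 each held at least 1 value of the kind that spots near background take, a ratio of small whole numbers, as did 7 of the 11 features with lower ratios and 6 of the 45 with higher ones. A further 6 named genes past the threshold, Csf2, Fap, Nefm, Rgs4, S1pr3 and Zc3hav1l, picked out after their values were seen, had ratios of both signs among their arrays.

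**Figure D1:**
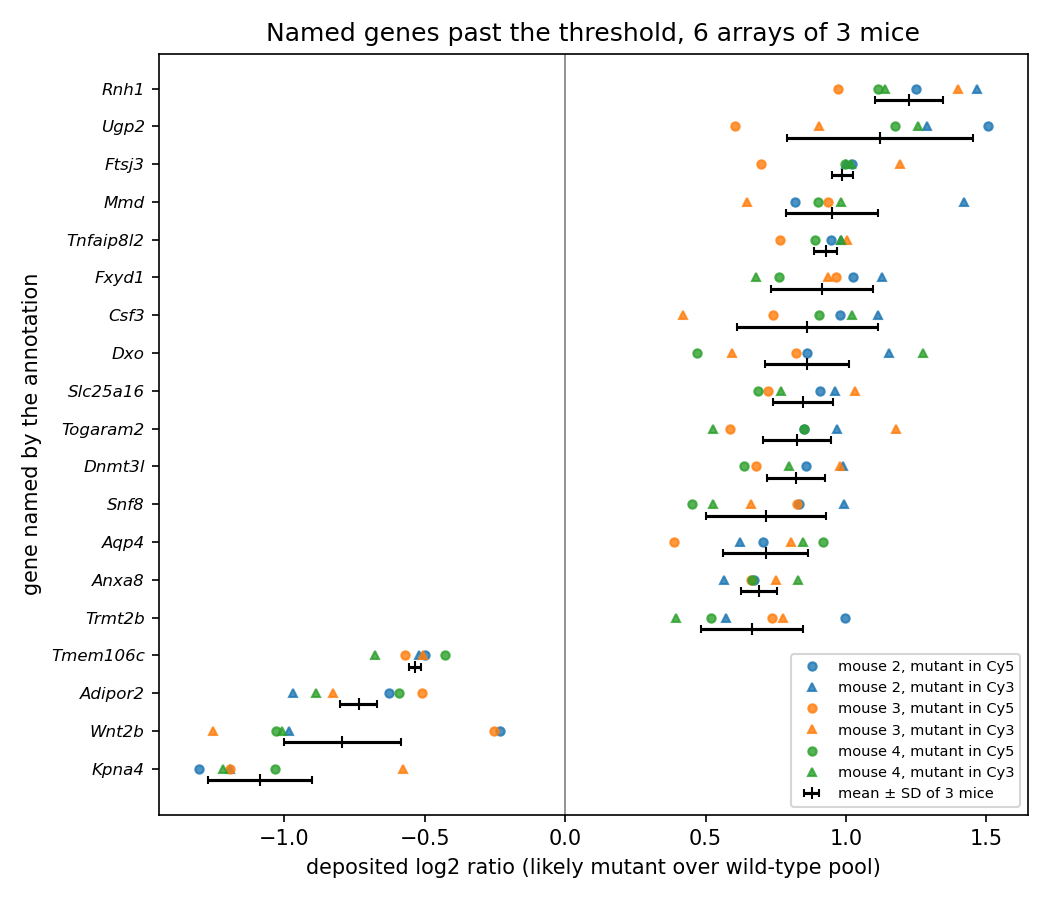
Log2 ratios, by array, of the 19 named genes past the threshold with the highest or lowest means among those with 1 sign on all 6 arrays, with circles for the mutant in Cy5, triangles for the mutant in Cy3, and colours for mice 2 to 4; black bars give the mean ± SD of 3 mice. Means run from -1.09 for Kpna4 to 1.22 for Rnh1.

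Over 3741 pairs of probes that name the same gene, the correlation of their mean ratios was -0.0018, inside the range of -0.034 to 0.033 that shuffled names gave. The gene names rest on the platform annotation and had no support from these values, so each value belongs to its probes, and its gene only as far as that annotation holds. The count was 26, with 20 higher and 6 lower, when each array was centred on its median, all of them among the 56. It was 24 without mouse 3, of which 16 were among the 56, 1 without mouse 2, of which 0 were, and 0 without mouse 4. On all 3 mice it was 0 with an unmoderated test, which has few degrees of freedom and so little power with 3 mice. That test gave 1310 features at an unadjusted p under 0.05. The moderated test gave 1666, and 840 would be expected with no effect. The count was also 0 with a variance trend and robust estimation. That trend ran on the size of the mean ratio, not on intensity. The spread assumed for a feature thus depended on the ratio being tested.

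None of the 30 gene lists, fixed before the data were examined, passed limma's camera test at an adjusted p under 0.05, and 0 of their 839 measured genes passed over all features. At an unadjusted p under 0.05 there were 3 such lists. The list tests rely on the gene names, which had no support from these values. If names do not match spots, a list holds arbitrary probes. A list that did not pass then says nothing about the process it is named for. Cholesterol synthesis genes had the lowest camera p, 0.0119 (adjusted 0.356), with 14 of 17 members above 0. Of all features, 59.5% were above 0. Mvk at 0.44 ± 0.19, Pmvk at 0.33 ± 0.12 and Scap at 0.32 ± 0.11 passed when adjusted over the list alone. Neutrophil markers followed at a camera p of 0.0445 (adjusted 0.491). Of their 11 measured members 8 were above 0, and Elane at 0.58 ± 0.31 and Mmp8 at 0.32 ± 0.10 passed adjusted over the list alone. For cytochrome P450 and xenobiotic metabolism the camera p was 0.0491 (adjusted 0.491), toward lower ratios, with 13 of 26 members above 0. In that list Cyp2d22 at -0.41 ± 0.10, Ugt1a6a at -0.43 ± 0.20 and Ces1c at 0.36 ± 0.19 passed adjusted over the list alone. Cyp2d22 differed in sign between orientations, with a mean of 0.09 on arrays with the mutant in Cy5 and -0.91 on those with it in Cy3. With an estimated correlation the lowest adjusted p over the lists was 0.962 and 0 lists had an unadjusted p under 0.05, and limma's fry gave a lowest adjusted p of 0.213 with 3 lists at an unadjusted p under 0.05, which were oxidative phosphorylation (fry p = 0.0160), neutrophil markers (fry p = 0.0173) and antigen presentation (fry p = 0.0213). The fry p was 0.0552 for cholesterol synthesis and 0.371 for cytochrome P450 and xenobiotic metabolism. Over all lists, 16 genes passed adjusted over their list alone, and 10 of them had 1 sign on all 6 arrays.

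The lists of fibrosis and of the bile duct did not pass, which given the limit on gene names is no evidence that these processes were unchanged. Of 44 extracellular matrix genes 25 were above 0 (camera adjusted p = 0.905), and adjusted over the list alone Dcn at -1.02 ± 0.60 and Ltbp2 at -0.36 ± 0.11 passed. Col1a1 had -0.08 ± 0.36, Col1a2 0.12 ± 0.03, Col3a1 0.07 ± 0.03 and Timp1 -0.08 ± 0.19 (SD, n = 3 each). In 25 stellate cell and fibroblast markers (camera adjusted p = 0.905) the lowest p belonged to Tgfb2 at -0.93 ± 0.75 and Cnn2 at 0.31 ± 0.18. In 27 cholangiocyte markers (camera adjusted p = 0.941) these were Wfdc2 at 0.24 ± 0.11 and Cldn4 at -0.20 ± 0.14, and Krt19 had -0.07 ± 0.06. The 36 progenitor, fetal and tumour-associated genes (camera adjusted p = 0.941) were led by S100a6 at 0.36 ± 0.09 and S100a11 at 0.22 ± 0.04.

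Immune and endothelial lists did not pass either. The camera adjusted p was 0.905 for 28 macrophage and monocyte markers, 20 lymphocyte markers, 24 endothelial markers, 34 chemokine and inflammatory signalling genes, 19 antigen presentation genes and 22 interferon response genes. Itgam at -0.37 ± 0.09 passed adjusted over the macrophage list alone, beside Cyba at 0.23 ± 0.13. Its mean was 0.02 on arrays with the mutant in Cy5 and -0.77 on those with it in Cy3. The lymphocyte members with the lowest p were Cd5 at -0.47 ± 0.38 and Cd3g at 0.17 ± 0.08, the endothelial ones Eng at -0.39 ± 0.20 and Vwf at -0.24 ± 0.10, and the chemokine ones Cxcl14 at -0.33 ± 0.12 and Ccl21a at 0.32 ± 0.14. For antigen presentation they were H2-Q10 at 0.23 ± 0.15 and Psmb9 at 0.11 ± 0.04, and for the interferon response Bst2 at 0.26 ± 0.06 and Irf8 at -0.16 ± 0.09. Vwf had a mean of 0.08 on arrays with the mutant in Cy5, and ran from -0.88 to -0.36 on those with it in Cy3. Of 28 acute phase proteins (camera adjusted p = 0.941), Hp, which encodes haptoglobin, at 0.54 ± 0.18 and Itih2 at -0.37 ± 0.17 passed adjusted over the list alone, and Lcn2 had 0.10 ± 0.11.

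Lists of bile and lipid metabolism gave camera adjusted p values of 0.941 for 20 bile acid synthesis genes, 11 hepatocyte bile salt and lipid transporters and 29 genes of fatty acid oxidation and PPAR alpha, and of 0.905 for 38 phospholipid and 31 fatty acid and triglyceride synthesis genes. Cyp27a1, a mitochondrial enzyme of bile acid synthesis, had 0.07 ± 0.09, and Nr0b2, which encodes the repressor SHP, 0.01 ± 0.20. The bile acid members with the lowest p were Nr1i2 at 0.17 ± 0.06 and Nr5a2 at -0.15 ± 0.09, and the transporters Abcb11 at 0.14 ± 0.10 and Scarb1 at 0.18 ± 0.32. Scarb1 reached 0.97 on the array of mouse 3 with the mutant in Cy3 and was -0.006 without mouse 3. Mat1a had 0.31 ± 0.11 and Lpcat1 0.31 ± 0.21 in phospholipid metabolism, Thrsp -0.36 ± 0.21 and Mogat1 0.21 ± 0.07 in lipid synthesis, and Acaa1a 0.18 ± 0.13 and Ech1 0.18 ± 0.16 in fatty acid oxidation. Scd1 stood at -0.01 ± 0.22 and Cyp4a14 at 0.01 ± 0.11. Cyp7a1, Cyp8b1, Slc10a1, Abcc2, Abcg5, Abcg8, Spp1 and Acta2 had no probe of that name.

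The lists of hepatocyte and general cell functions gave camera adjusted p values of 0.905 for 40 glutathione and NRF2 targets, 22 sex-dependent liver genes, 62 cell cycle genes, 35 genes of endoplasmic reticulum stress, 61 of oxidative phosphorylation and 56 ribosomal proteins, and of 0.941 for 47 differentiated hepatocyte functions. Fkbp11 at 0.46 ± 0.04 and Ero1a at 0.36 ± 0.02, both of protein folding in the endoplasmic reticulum, passed adjusted over their list alone. The other members with the lowest p were Gss at 0.32 ± 0.10 and Esd at -0.28 ± 0.13, Hgd at 0.29 ± 0.09 and Apoc1 at 0.22 ± 0.06, Nudt7 at 0.18 ± 0.09 and Cyp7b1 at -0.12 ± 0.10, Mcm5 at 0.37 ± 0.13 and Ccnd2 at -0.42 ± 0.39, Ndufb3 at 0.32 ± 0.14 and Atp5j2 at 0.32 ± 0.15, and Rps16 at 0.30 ± 0.02 and Rpl27 at -0.29 ± 0.17. Ccnd2 was lowest on the array of mouse 3 with the mutant in Cy3, at -1.58, and stood at -0.23 without mouse 3. Markers of tissue that a liver piece could carry also gave a camera adjusted p of 0.905. Zg16 at 0.36 ± 0.11 passed adjusted over the 13 pancreas markers alone, beside Clps at 0.22 ± 0.13, and the other lists were led by Casq1 at 0.30 ± 0.09 and Pvalb at 0.35 ± 0.19 of 22 muscle markers, Plin4 at 0.17 ± 0.11 and Adipoq at 0.13 ± 0.08 of 14 adipose tissue markers, and Tspo2 at 0.22 ± 0.22 and Sptb at 0.15 ± 0.04 of 12 red blood cell markers. In the cholangiocyte, endothelial and fatty acid oxidation lists the median over the median of all named genes and the camera test differed in sign.

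**Figure D2:**
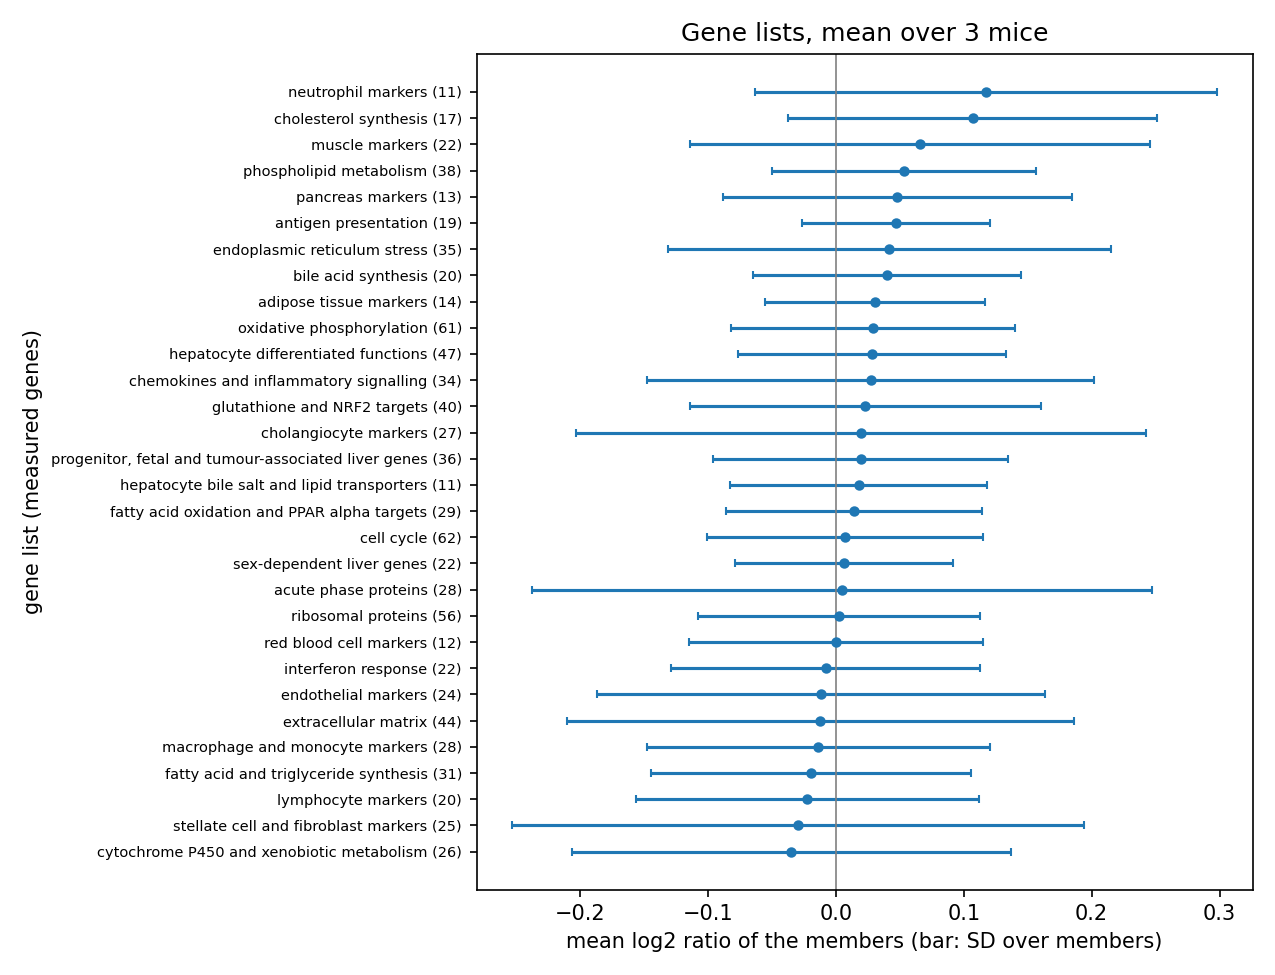
Mean log2 ratio of the measured members of each of the 30 gene lists, with bars for the SD over members and the number of measured genes in brackets. The means lie between -0.03 and 0.12, and the bars show how far single members differ, not the error of a list's mean.

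Arrays of 1 dye orientation were more alike than the 2 arrays of a mouse. Over probes, which are not independent replicates, arrays of 1 orientation from different mice correlated at 0.215 on average, and arrays of opposite orientation at -0.021. The 2 arrays of mice 2, 3 and 4 correlated at 0.10, -0.13 and 0.01. The difference between orientations, tested in the same way, passed for 26 features, all with 1 sign, and for 3 after median centring; 1 of the 26 was also among the 56. The array of mouse 3 with the mutant in Cy3 had the widest spread of log ratios, with an SD of 0.561 against 0.244 to 0.331 on the other hybridisations. With mouse 3 taken from its Cy5 array alone, 23 features passed, 21 higher and 2 lower.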

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

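The sign patterns of the mice, the test on neighbouring probes and the low-signal test over all calls were fixed before their results were seen. The other tests in this part were chosen only after the result was seen. With 7 separate hybridisations, the array of mouse 3 with the mutant in Cy3 stood apart in the spread of its log ratios. Its SD was 0.561 against 0.331 for the next widest. For each measure, chance marks about 1 in 20 such groups. The counts of measured and missing values and the medians were screened too, so a mark on some measure is more frequent. Groups of 3 mice were not tested for single values. The comparison did not use the hybridisation of mouse 1, yet in its first column 47 of the 54 called features measured there had the sign found in mice 2 to 4, against 49.0% of all features. Of the positive calls 42 of 44 were positive there, with a median of 0.72, and of the negative calls 5 of 10 were negative, with a median of -0.15; the column holds 1 dye orientation, so a dye effect is not cancelled in it, and it was measured against the same pool, so any deviation of the pool recurs in it. The value that no effect would give was not computed, and the agreement is no independent evidence of the genotype.

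Probes that name the same gene did not share their ratio, with a correlation of -0.0018 over 3741 pairs, inside the range of shuffled names. Measurement noise alone is argued against by the mean correlation between mice over probes of 0.192, which shows that a part of each spot's ratio recurs. Position on the array masking the gene's part could not be decided, because neighbours were taken by probe number and spot coordinates were not used. After the running median of 51 such neighbours was subtracted, the correlation was -0.015, still inside the range of shuffled names. Neighbours by number correlated at 0.086 in mean ratio, 0.290 in dye part and 0.198 in log SD. Names that do not correspond to the spots remain a candidate explanation: the dye part correlated at 0.0084 and the log SD at 0.024 between probes of 1 gene, both also inside the range of shuffled names. Clones of 1 gene that hybridise differently were not tested, and no biological explanation was tested.

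Most called features had positive ratios, 45 of 56, though on arrays with the mutant in Cy3 alone 13 of 18 calls were negative. Median centring takes off an offset of whole arrays, and 76.9% of calls, 20 of 26, were still positive after it (95% Wilson interval 57.9 to 89.0). Those 20 calls therefore do not rest on the array medians alone. The interval treats features as independent, though they share 3 mice and 1 pool and all 26 were among the 56. It cannot decide whether an offset adds to the share. Spots near background, seen as ratios of whole numbers up to 4, held 23.2% of all calls against 27.3% of features not called. The share of calls lay between the bounds set beforehand. Such spots held 63.6% of the negative calls, 7 of 11, and 13.3% of the positive ones. Low signal is thus a candidate explanation for the negative calls. Most positive calls held no such value, which argues against spots of that kind for them. Weak spots with larger whole numbers would not be seen, so low signal in general stays open for the positive calls. Positive calls correlated at 0.110 over the 6 arrays, against a median of 0.067 and a top 5% of 0.134 in random sets of like spread. Sets of uncalled positive features with an unadjusted limma p under 0.05 gave a median of 0.099 and a top 5% of 0.185. A sequence shared by the probes stays open, and so does the genotype, untested. The 3 mice allow 4 sign patterns, too few for a share under 0.05; 1 of the 4, the real one, reached 56 calls and the highest other gave 1.

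The dye-swapped arrays of a mouse hardly correlated. A dye effect as large as that of the genotype could account for this: arrays of 1 orientation from different mice correlated at 0.215 and those of opposite orientation at -0.021. Columns with the mutant in Cy3 that run the other way could not be told apart from it by array correlations. The deviations of the 2 arrays of a mouse correlated at 0.028, the highest of only 6 pairings, of which the next gave 0.015. The signs of the placeholders and of the mouse 1 copy are those that a sign change already made for these columns would give. They were the basis for using the columns as deposited, and the direction remains likely, not stated. No biological explanation was tested.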

How the results depend on the processing

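The turned Cy3 columns, mouse 1 from either column, mouse 3 from its Cy5 array and kept placeholders were chosen after seeing the data. The count of 56 changed features ranged from 0 to 24 with 1 of mice 2 to 4 left out, which leaves 2 mice; leaving out mouse 1 is the fit as reported. It was 26 with median-centred arrays, 28 centred and scaled, 132 with 6 arrays and mouse as a random block, 18 on arrays with the mutant in Cy3, 123 with each probe on its own, 31 where 1 array of a mouse was enough, 0 with a variance trend, 107 with mouse weights, 3 at an adjusted p under 0.01, 135 under 0.10, 6 against a fold of 1.2, 0 with an unmoderated test (1310 features at an unadjusted p under 0.05), 66 with mouse 1 from its first column (58 higher and 8 lower), 2 with mouse 1 from its second column, 23 with mouse 3 from its Cy5 array, and 0 with placeholders kept. It was 39 on arrays with the mutant in Cy5, with 38 positive, while 13 of the 18 on Cy3 arrays were negative. With the Cy3 columns turned it was 44 for 4 mice, 26 for mice 2 to 4, and 3 for 4 mice after centring. The variance trend ran on the size of the mean ratio, not on intensity. The unmoderated test has little power with 3 mice. The fit with mouse as a random block had a within-mouse correlation of 0.024, so it counted the 6 arrays almost as separate animals. The dye effect passed for 3 features after median centring against 26. All 26 calls after centring were among the 56, as were 16 of the 24 without mouse 3 and 0 of the 1 without mouse 2. The cause of these differences was not tested.

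No alternative brought a gene list past the threshold, with lowest adjusted p between 0.111 and 0.997. The Abcb4 ratio passed in none, from -0.47 to 0.20; it was positive only with the Cy3 columns turned. For the 29 called named genes, 240 of 607 comparisons stayed past the threshold with the same sign, 331 fell short and 36 turned sign, 34 of them with the Cy3 columns turned. That fit takes the difference between orientations, and for mice 2 to 4 it is the test of the dye effect, so genes with like ratios in both orientations come near 0 by construction. With Cy3 columns turned for 4 mice these were Csf2 at 0.66, Fap 0.72, Rgs4 0.51 and Zc3hav1l 0.50, and after centring Csf2 0.62, Fap 0.69, Rgs4 0.48, Zc3hav1l 0.47, Dxo -0.0081, Frat2 -0.0021 and Parp11 -0.011. For mice 2 to 4 with Cy3 turned they were Rnh1 -0.11, Ugp2 -0.028, Ftsj3 -0.082, Mmd -0.065, Tnfaip8l2 -0.061, Dxo -0.15, Slc25a16 -0.075, Togaram2 -0.064, Dnmt3l -0.099, Snf8 -0.012, Aqp4 -0.043, Anxa8 -0.024, Wnt2b 0.29, Adipor2 0.16, Tmem106c 0.034, Csf2 0.66, Fap 0.58, Frat2 -0.076, Guca2b -0.031, Parp11 -0.086, Rgs4 0.31, Sarnp -0.039 and Zc3hav1l 0.55. Nefm was -0.016 on Cy3 arrays alone and Wnt2b 2.00 with placeholders kept. Of named genes that had not passed, 7 of 1470 comparisons passed, 161 turned sign without passing, and 0 passed with the sign turned.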

Other observations

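Members of the gene lists that missed the threshold in the comparison passed it under a few other settings chosen before the data were examined, with the sign unchanged. Fkbp11, a folding enzyme of the endoplasmic reticulum, stood at 0.46 on the log2 scale and had a limma adjusted p of 0.0585 as reported, 0.0176 with 6 arrays and mouse as a random block, 0.04996 with each probe on its own and 0.0441 with mouse weights, and its ratio was positive on 6 of 6 arrays. Hp, which encodes the acute phase protein haptoglobin, stood at 0.54 with a limma adjusted p of 0.0698 as reported and 0.0267 with the random block. It was also positive on 6 of 6 arrays. The fit with the random block had a within-mouse correlation of 0.024, so it counted the 6 arrays of 3 mice almost as separate animals. Its lower p values are no added support. With each probe on its own, 1 probe reached -0.82 for Eng, an endothelial co-receptor of the TGF-beta family (adjusted p = 0.0435), and 1 reached -0.75 for the chemokine Cxcl14 (adjusted p = 0.0192), while the other probe of each stood at 0.04 and 0.10. As gene means, Eng was at 0.02 on arrays with the mutant in Cy5 and -0.80 on those with it in Cy3, and Cxcl14 at -0.07 and -0.59. Tgfb2 reached -1.36 without mouse 3 (adjusted p = 0.0170), which leaves 2 mice. Of 21 settings, Fkbp11 passed in 3, with an adjusted p from 0.0176 to 0.765, and Hp in 1, from 0.0267 to 0.766. Eng, Cxcl14 and Tgfb2 passed in 1 each, with an adjusted p of up to 0.954, 0.809 and 0.965. The ratio was negative on 4 of 6 arrays for Eng and on 5 of 6 for Cxcl14 and Tgfb2. The limit on gene names holds for these genes too.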
